A study of Mus musculus with 15 samples.

How the data were processed

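Bulk RNA-seq had been done on macrophages sorted by flow cytometry from primary brain tumours of mice with a PDGFB-driven glioma on an Ink4a/Arf-knockout background. Per the labels' protocols, RNA was isolated from the sorted cells with a column kit that included a DNase step, and RNA integrity numbers were above 8. Libraries were made from a few nanograms of RNA by oligo-dT priming and template switching, per the labels' protocols. The deposited table held whole-number read counts per gene for the 15 libraries, not normalized, with Ensembl gene identifiers, symbols and gene coordinates, per the file header. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the strand setting were not given in the sources used here, so counts of overlapping and antisense genes could not be told apart. Values of genes with near-identical copies (H2 class II genes, Klr receptors, Ms4a, Ifitm and Pilrb2) are uncertain wherever they are named below, also where this is not repeated. Gene coordinates were those of the deposited table. Of the 14843 genes tested, 14831 were found by identifier in the GENCODE M21 annotation, and 14701 of these (99.1%) had the same start and end there.

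Each library was assigned to 1 of 4 groups by its title: microglia or monocyte-derived macrophages (MDM), each lipid-laden or not. The numbers in the titles (224, 221, 431 and 718) served as replicate numbers. Each group had 4 libraries, except lipid-laden MDM with 3, because a lipid-laden MDM library of number 431 was not analysed here. All columns of the table belonged to these libraries, and no entry was without a gene. The total count per library ranged from 7798952 to 11419338, and total counts are given by group with the results. Within each group, replicates differed by far more than sampling noise (smallest chi-square per degree of freedom 17.3, over genes with a count of at least 10), so none was counted as a repeat of another.

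Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM normalization and Benjamini-Hochberg adjustment. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 14843 of 55486 genes. All 15 libraries entered a single fit with 1 coefficient per group and no covariate, and a gene was called at an adjusted p under 0.05 with no fold minimum. The contrasts taken from this fit were lipid-laden against non-lipid-laden microglia, the same for MDM, MDM against microglia without and with lipid load, and the difference of the lipid-laden effect between MDM and microglia. Levels are given as CPM, counts scaled to the same total per library, on TMM-scaled library sizes, as mean ± SD over libraries. Log2 fold changes carry an approximate standard error (SE). It was derived from the test, as the size of the log2 fold change over the square root of its quasi-likelihood F statistic. For genes at or near 0 counts it is not a reliable measure of error. Where a group had 0 counts, a fold is given as a bound against 3 counts over the group, and with 1 to 3 counts as a ratio of summed CPM with a 95% exact binomial interval. These bounds and intervals covered counting error only, since the libraries carried no molecular identifiers.

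Gene lists were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, and beside it with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The 34 lists, with 632 entries and 595 distinct symbols, covered lipid handling, macrophage states and stress, markers of other cells and mitochondrially encoded RNA. P-values were adjusted over the lists within a contrast. The groups, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined. By that rule the text names, per contrast, the 10 genes with the largest increase and the 10 with the largest decrease among called genes with an average log2 CPM of at least 3, a symbol that is not that of a predicted gene, and the same direction in every number-matched pair (5 and 5, without the pair condition, for the difference of effects). It also names 12 fixed genes, up to 4 members with the smallest p per list and, where fewer than 5 genes passed, the 5 with the smallest p.

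The titles do not say whether a shared number means a shared animal. Deviations from group means correlated across genes for same-numbered microglial libraries with and without lipid load (r = 0.124 to 0.256 over 4 pairs, against -0.200 to 0.0941 for other numbers) and for the lipid-laden pairs of both origins (0.107 to 0.168, against -0.108 to 0.0291), but less so for the MDM pairs (0.0272 to 0.123) and the non-lipid-laden pairs (0.0152 to 0.150). The Y-linked gene Ddx3y was expressed and Xist was near 0 in all libraries of number 224, and the reverse held for the other numbers. On these grounds the numbers were treated as pairing the libraries. Values of a fit with the number as a replicate block stand beside named genes and lists whose call they change. They also stand beside counts of called genes per contrast that they move by over 1.5 times. Counts of called list members with the block are given only for lipid load in microglia, and in other contrasts they may differ from those printed. Which values to print was settled after the counts of both fits had been seen, and the fit without the block, set in advance, remained the reference. The samples are not labelled as separate animals, so p-values measure only the spread between these samples, which may in part be technical.

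Before use, each test was tried on simulated counts with 200 genes changed. These counts were drawn once per contrast, with the spread per gene that edgeR had estimated and no effect of the replicate number. They may therefore favour edgeR, and they cannot judge fits to paired libraries. For lipid-laden against non-lipid-laden microglia, over 14107 genes, edgeR recovered 27% of genes changed 2-fold and 63% of those changed 4-fold with 3 false calls, while DESeq2 1.42.0 made 43 false calls. For the MDM contrast, over 14106 genes, edgeR recovered 21% and 55% with 2 false calls and DESeq2 made 31. Alternatives were DESeq2, limma-voom, RLE size factors, no filter and a stricter filter on low counts, only the groups compared, counts thinned to the shallowest library, the replicate block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.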

Results

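The data were read counts per gene from 15 bulk RNA-seq libraries of macrophages sorted from mouse gliomas driven by the growth factor PDGFB. The labels divided the cells by origin, into microglia, the resident macrophages of the brain, and monocyte-derived macrophages (MDM), which enter from the blood, and by whether they were sorted as lipid-laden. There were 4 libraries of non-lipid-laden microglia, 4 of lipid-laden microglia, 4 of non-lipid-laden MDM and 3 of lipid-laden MDM. The stain and the gate that defined lipid load are not given in the sources used here. Total counts were 7842531 to 9658143 for non-lipid-laden microglia, 8962885 to 9797627 for lipid-laden microglia, 7798952 to 11419338 for non-lipid-laden MDM and 9306839 to 10699235 for lipid-laden MDM.

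The first principal component of log2 CPM, with 36.2% of the variance, separated the origins. Non-lipid-laden MDM lay between 111 and 127 on it, and microglia between -71.3 and -60.4 without and between -80.9 and -66.9 with lipid load. The 3 lipid-laden MDM libraries lay between these, at 7.96 to 35.9. On the second component, with 11.1% of the variance, both lipid-laden libraries numbered 221 stood apart from the others, at -119 for microglia and -67.4 for MDM. Mitochondrially encoded RNA made up 0.756 ± 0.156% of counts in non-lipid-laden microglia, 0.969 ± 0.106% in lipid-laden microglia, 0.543 ± 0.0920% in non-lipid-laden MDM and 0.623 ± 0.129% in lipid-laden MDM (SD). The number of genes with at least 1 count was 17286 ± 374, 16506 ± 1068, 16181 ± 703 and 16368 ± 840 in the same order.

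**Figure D1:**
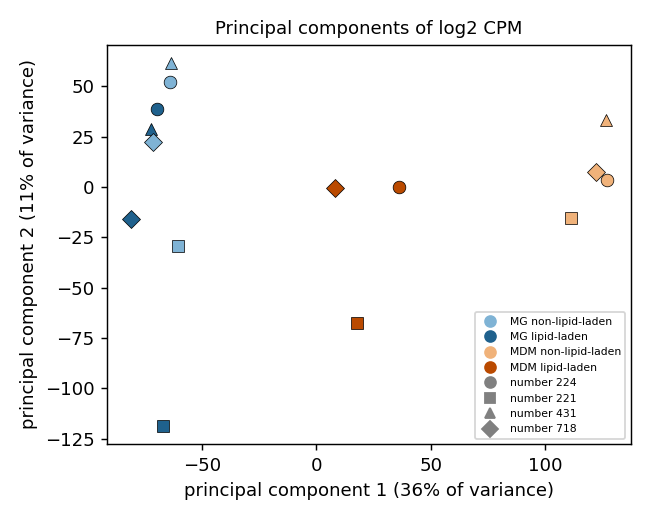
Position of each of the 15 libraries on the first and second principal components of log2 CPM (36.2% and 11.1% of the variance), coloured by group and with the replicate number as the marker shape. The lipid-laden MDM libraries lie at 7.96 to 35.9 on the first component, between non-lipid-laden MDM (111 to 127) and microglia (all below -60).

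Non-lipid-laden MDM and microglia were compared first, to give the difference of origin apart from lipid load. Ccr2, the chemokine receptor that draws monocytes into tissue (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), was at 959 ± 243 CPM in MDM and 8.46 ± 3.85 CPM in microglia (SD, n = 4 each), a log2 fold change of 6.81 (SE 0.63, edgeR adjusted p = 2.51e-06). P2ry12, the purinergic receptor that marks resting microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), was lower in MDM, at 147 ± 24.8 against 980 ± 183 CPM (log2 fold change -2.73, SE 0.30, edgeR adjusted p = 1.25e-05). Tmem119, another microglial marker (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), was lower by a log2 fold change of -2.38 (SE 0.31, edgeR adjusted p = 5.05e-05). Itga4, the integrin subunit used to tell MDM from microglia (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123), was higher in MDM by 4.47 (SE 0.99, edgeR adjusted p = 0.00395). In all, 3442 of 14843 genes differed, 1584 higher and 1858 lower in MDM, of which 1032 and 1451 differed at least 2-fold.

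Of 24 MDM markers, 22 were higher in MDM and none was lower, and 23 were higher when adjusted over the list alone (median log2 fold change 4.07, camera adjusted p = 3.98e-18, adjusted p = 0.0202 with an estimated correlation). Examples were Tgfbi, a secreted matrix protein (2.99), Plac8 (5.13), Ahnak (4.11) and Ccr2. All 13 genes of MHC class II presentation were higher, also when adjusted over the list alone (median 3.42, camera adjusted p = 3.92e-16, adjusted p = 0.0214 with an estimated correlation). H2-DMb2 (5.35, SE 0.33) and H2-Oa (3.43, SE 0.29) were examples, and reads that they share with close relatives were not set apart. Of 22 homeostatic microglia genes 21 were lower, 21 when adjusted over the list alone (median -2.15, camera adjusted p = 1.72e-15, adjusted p = 0.147 with an estimated correlation). They included Sall1, a transcription factor of microglial identity (-4.28, SE 0.33), Ecscr (-3.86) and Gpr34 (-3.28).

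Markers of other cells differed too. Of 12 dendritic cell genes, 10 were higher in MDM and 1, Siglech, also on the homeostatic microglia list, was lower (-3.10), with the same counts when adjusted over the list alone (median 5.18, camera adjusted p = 3.27e-06, adjusted p = 0.147 with an estimated correlation, and 0.0254 with that and the replicate block). Kmo, an enzyme of tryptophan breakdown, was higher by 8.27 (SE 0.52), Dpp4 by 6.55, Itgae by 6.79 and Ccr7, the receptor that guides dendritic cells to lymph nodes, by 5.17. Of 15 T and NK cell genes 8 were higher, 12 when adjusted over the list alone (median 4.55, or 4.16 with genes at 0 or few counts at their bound, camera adjusted p = 2.85e-06, adjusted p = 0.147 with an estimated correlation, and 0.0173 with that and the block). Among them, Il2rb was higher by 4.95 and Nkg7 by 4.16, and Gzmb, with 146 counts in MDM and 0 in microglia, was at least 43.0-fold higher. Of 17 progenitor and glioma cell genes 15 were lower in MDM, 16 when adjusted over the list alone (median -4.35, or -4.28 with bounds, camera adjusted p = 1.04e-05, adjusted p = 0.26 with an estimated correlation). Among them were Cspg4 (-4.28), Olig1 (-3.31), Ptprz1 (-4.35) and the PDGF receptor gene Pdgfra (-5.16).

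Of 26 proliferation genes 23 were lower in MDM and 1 was higher, with 1 higher and 24 lower when adjusted over the list alone (median -1.80, camera adjusted p = 2.98e-10, adjusted p = 0.26 with an estimated correlation). Among them were the mitotic genes Ccnb1 (-2.73) and Cdc20 (-2.32). Of 35 lysosome genes 15 were lower, 16 when adjusted over the list alone. Examples were the cathepsin genes Ctsl (-1.82) and Ctsd (-1.77) and Cd63 (-1.39). The median was -0.25 (camera adjusted p = 4.91e-05, adjusted p = 0.262 with an estimated correlation). Of 23 disease-associated microglia and lipid-associated macrophage genes, 11 were lower and 4 higher, with the same counts when adjusted over the list alone (median -0.49, camera adjusted p = 0.00265, adjusted p = 0.147 with an estimated correlation). Of 19 lipid uptake genes, 8 were lower, among them Lpl, Trem2 and Mertk (-1.65), and 2 higher, with 9 and 3 when adjusted over the list alone (median -0.62, camera adjusted p = 0.0439, adjusted p = 0.328 with an estimated correlation, and camera adjusted p = 0.0784 without MDM library 431). Lpl, the lipoprotein lipase gene, was lower in MDM than the 257 ± 22.3 CPM of microglia (-3.26, SE 0.27, edgeR adjusted p = 9.01e-07). Trem2, a lipid-sensing receptor, was at 318 ± 31.9 against 909 ± 118 CPM (-1.52, SE 0.15, edgeR adjusted p = 4.66e-06).

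Of 25 cholesterol synthesis genes 8 were higher in MDM and none lower, with 9 higher and 1 lower when adjusted over the list alone. Among the higher were Cyp51 (1.87) and Pmvk (1.50). The median was 0.62 (camera adjusted p = 0.000756, adjusted p = 0.202 with an estimated correlation). Of 27 interferon response genes 9 were higher and 1 lower, with 11 and 1 when adjusted over the list alone. Higher genes included Ifitm3 (1.82) and Isg20 (2.41). The median was 0.67 (camera adjusted p = 6.6e-07, adjusted p = 0.343 with an estimated correlation). Of 28 oxidative phosphorylation genes 7 were higher, 8 when adjusted over the list alone (median 0.23, camera adjusted p = 0.00161, adjusted p = 0.51 with an estimated correlation). By contrast, 4 of 10 mitochondrially encoded genes were lower, 5 when adjusted over the list alone (median -0.64, camera adjusted p = 0.021, adjusted p = 0.424 with an estimated correlation, and camera adjusted p = 0.0683 without microglial library 431). The immunoregulatory list was not called (5 of 22 genes higher and 3 lower, 7 and 3 when adjusted over the list alone, camera adjusted p = 0.0668), except with the replicate block (camera adjusted p = 0.0176, adjusted p = 0.218 with an estimated correlation). Abca1, the cholesterol efflux transporter (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895), was lower in MDM (-1.12, SE 0.16, edgeR adjusted p = 0.000124), and Plin2, Gpnmb, Apoe, Cd36 and Spp1 did not pass (edgeR adjusted p = 0.811, 0.665, 0.636, 0.455 and 0.354).

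The largest increases among the genes named by rule were of genes nearly absent from microglia. The vitamin D receptor gene Vdr had 2500 counts in MDM and 0 in microglia, at least 737-fold higher. The same held for the cadherin gene Cdh17 (at least 561-fold), Igha (at least 526-fold), Krt80 (at least 437-fold) and Klri2 (at least 340-fold). With 1 to 3 counts in microglia, the ratio was 1657 for Hepacam2 (95% counting interval 567 to 8036), 2012 for Htr7 (361 to 79520), 871 for Gpr141 (298 to 4225) and 640 for Papss2 (115 to 25330), and Gpr132 was higher by a log2 fold change of 8.77 (SE 0.89). On the other side, Lox, a collagen cross-linking enzyme with 0 counts in MDM against 420 in microglia, was at least 158-fold lower. Smtnl2 had 2 against 327 counts, a ratio of 185 in favour of microglia (counting interval 50.8 to 1533). The others were Fkbp14 (-6.79), Cdk18 (-6.40), Tmem44 (-6.39), Cntn1 (-5.83), Sall3 (-5.61), Gpm6a (-5.54), Naalad2 (-5.53) and Plpp3 (-5.39), with edgeR adjusted p from 3.7e-06 to 0.003.

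Lipid-laden microglia were then compared with non-lipid-laden microglia, to describe resident cells sorted for their lipid load. All 26 hypoxia and glycolysis genes had a positive log2 fold change in lipid-laden microglia (median 0.69), among them Ndrg1, a hypoxia-induced gene at 77.9 ± 40.3 against 19.4 ± 6.42 CPM (2.00, SE 0.37), and the glycolytic genes Ldha (0.62, SE 0.14) and Pkm (0.60, SE 0.14). The list was called (camera adjusted p = 5.27e-22), with adjusted p = 0.0882 with an estimated correlation. All 18 genes of the immediate early and dissociation response list, called immediate early genes below, were negative (median -0.65, camera adjusted p = 5.49e-10, adjusted p = 0.155 with an estimated correlation). Whether handling of the tissue and cells moved them was not tested. Of 23 disease-associated and lipid-associated genes 20 were positive (median 0.21, camera adjusted p = 1.6e-07), and it was the only list that also held with an estimated correlation (adjusted p = 0.0332). Single genes did not pass in this comparison: edgeR called 0 of 14843 genes (smallest edgeR adjusted p 0.0717), with 1367 genes at an unadjusted p under 0.05, while limma-voom called 0, DESeq2 164 and edgeR without a filter 17.

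With the replicate block, edgeR called 119 genes, 60 higher and 59 lower in lipid-laden microglia, and DESeq2 and limma-voom with the block called 602 and 212. Without the block, leaving out lipid-laden library 224 gave 64 calls, and leaving out non-lipid-laden library 431 or 718 gave 2 each. With the block, the count was 17, 68, 13 or 0 without the libraries of number 221, 224, 431 or 718, so the last number decided whether any gene was called.

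The fixed genes did not pass in the edgeR fit without the block. Gpnmb, a transmembrane glycoprotein of lipid-associated macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), was at 663 ± 511 CPM with and 167 ± 174 CPM without lipid load (1.99, SE 0.70, edgeR adjusted p = 0.379). Plin2, which coats lipid droplets (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), was at 1180 ± 315 and 818 ± 237 CPM (0.53, SE 0.22, edgeR adjusted p = 0.488). Spp1, the osteopontin gene (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was at 3631 ± 1166 and 1955 ± 781 CPM (0.89, SE 0.28, edgeR adjusted p = 0.341), and passed with the block (edgeR adjusted p = 0.0276) and with DESeq2 (adjusted p = 0.0494). Lpl was at 461 ± 87.7 and 257 ± 22.3 CPM (0.84, SE 0.25, edgeR adjusted p = 0.301), and passed with DESeq2 (adjusted p = 0.0455). Apoe (0.00, SE 0.15), Trem2 (0.01, SE 0.15), Abca1 (0.22, SE 0.16), Cd36 (0.23, SE 1.21), P2ry12 (-0.49, SE 0.29), Tmem119 (-0.40, SE 0.29), Ccr2 (-1.19, SE 0.57) and Itga4 (-1.47, SE 1.00) had edgeR adjusted p of 0.547 or more. The 5 genes with the smallest p, which did not pass (edgeR adjusted p = 0.0717 each), were Selenbp1 (1.78, SE 0.29), Clk1 (-0.80, SE 0.13), A530064D06Rik (1.93, SE 0.33), Kynu, an enzyme of tryptophan breakdown with 0 against 98 counts (at least 35.9-fold lower), and Klrb1b with 2 against 106 counts (a ratio of 58.3 in favour of non-lipid-laden cells, counting interval 15.7 to 488). All of these passed with the block (edgeR adjusted p = 0.0153, 0.00533, 0.0199, 0.00533 and 0.0188), with DESeq2 and without a filter on low counts.

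**Figure D2:**
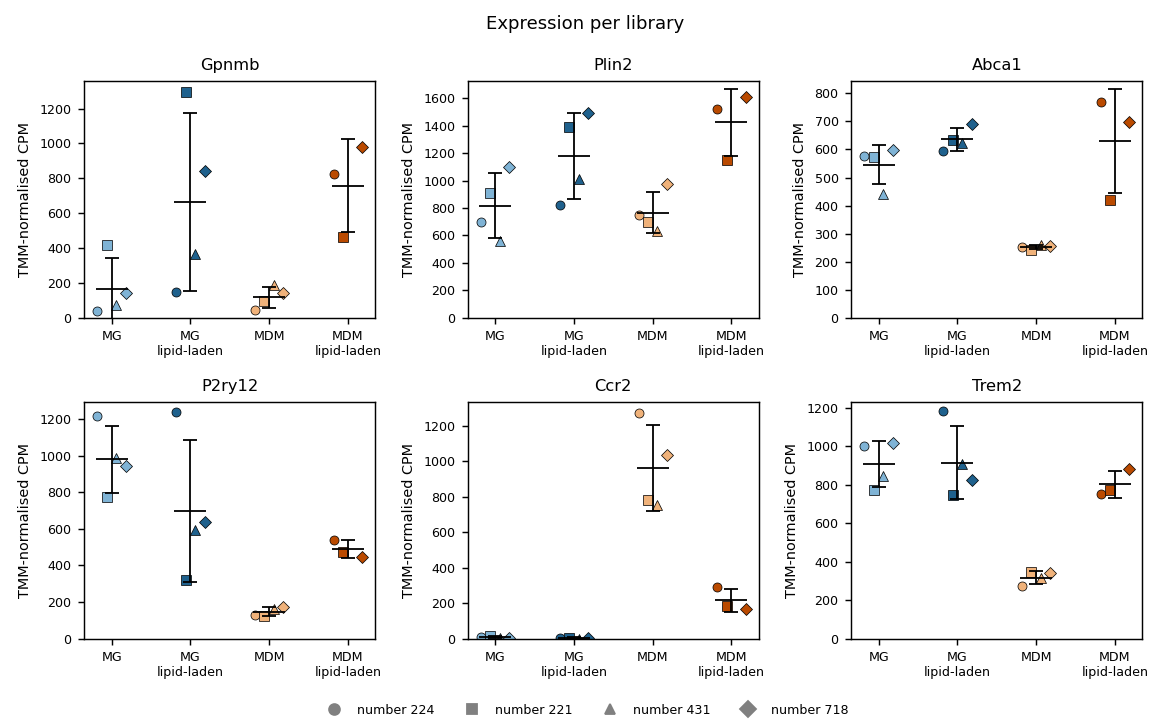
TMM-scaled CPM of Gpnmb, Plin2, Abca1, P2ry12, Ccr2 and Trem2 in each library by group, with lines at the mean ± SD and the replicate number as the marker shape; the lower bar of Gpnmb in non-lipid-laden microglia (167 ± 174) runs below the axis at 0. Trem2 was at 909 ± 118, 915 ± 192, 318 ± 31.9 and 802 ± 71.9 CPM in non-lipid-laden and lipid-laden microglia and non-lipid-laden and lipid-laden MDM.

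In single genes adjusted over the list alone, 20 of the 26 hypoxia and glycolysis genes passed, and 12 passed with the block over all genes. Of the 18 immediate early genes, 8 were lower when adjusted over the list alone and 7 were lower with the block, among them Btg2 (-0.96, SE 0.20), Atf3 (-0.54), Klf6 (-0.66) and Ier2 (-0.63), with edgeR adjusted p of 0.00533 to 0.0264 with the block. Of the disease-associated and lipid-associated genes 6 were higher when adjusted over the list alone and 5 with the block, among them Lgals3, the galectin-3 gene (1.43, SE 0.27), the fatty acid carrier Fabp5 (1.22, SE 0.22) and the endosomal glycoprotein Cd68 (0.42, SE 0.10). Of 19 lipid uptake genes, 5 of which the previous list also holds, 4 were higher when adjusted over the list alone (median 0.42, camera adjusted p = 5.65e-05, adjusted p = 0.0882 with an estimated correlation). Of 18 genes of the antioxidant regulator NRF2 and iron handling, 6 were higher when adjusted over the list alone (median 0.38, camera adjusted p = 9.57e-07, adjusted p = 0.0906 with an estimated correlation). Hmox1, which breaks down heme, was at 0.83 (SE 0.16). Of 18 lipid droplet genes, 2 were higher and 1 lower when adjusted over the list alone, and Hilpda, an inhibitor of lipolysis, was at 1.27 (SE 0.23). The median was 0.26 (camera adjusted p = 0.0409, adjusted p = 0.279 with an estimated correlation). That call was lost without lipid-laden library 221 (camera adjusted p = 0.106) or 718 (0.130) and without non-lipid-laden library 224 (0.134) or 431 (0.0810).

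Further lists were called with camera although none of their genes passed over all genes without the block, and each lost its call with an estimated correlation. Where no count adjusted over the list alone is given for one of these called lists, it was 0. Lysosome genes had a median of 0.16 (29 of 35 positive, camera adjusted p = 3.19e-05, adjusted p = 0.218 with an estimated correlation). Oxidative phosphorylation genes had 0.22 (28 of 28 positive, camera adjusted p = 1.63e-07, adjusted p = 0.277 with an estimated correlation). Proliferation genes had a median of 0.39 (camera adjusted p = 2.04e-06, adjusted p = 0.309 with an estimated correlation). Fatty acid oxidation genes had 0.24 (camera adjusted p = 0.00144, adjusted p = 0.102 with an estimated correlation). PPAR targets, 4 of them also on that list, had 0.31 (camera adjusted p = 0.0078, adjusted p = 0.102 with an estimated correlation). Targets of the sterol receptor LXR had a median of 0.27 (camera adjusted p = 0.00358, adjusted p = 0.279 with an estimated correlation), with Scd2 at 0.65 and higher when adjusted over the list alone, and 1 gene higher and 1 lower with the block. Matrix genes had a median of 0.48 (camera adjusted p = 0.00163, adjusted p = 0.218 with an estimated correlation), with 3 higher when adjusted over the list alone and 3 with the block. Inflammatory genes had a median of -0.25 (camera adjusted p = 0.00677, adjusted p = 0.218 with an estimated correlation). It was -0.34 without 1 member that had 3 counts or fewer in both groups. Il1b was at -0.69 (SE 0.14) and Cxcl1 at 1.54 (SE 0.33). Of the list, 1 gene was higher and 2 were lower both when adjusted over the list alone and with the block. Homeostatic microglia genes had a median of -0.28 (19 of 22 negative, camera adjusted p = 0.000572, adjusted p = 0.512 with an estimated correlation), with 1 gene lower with the block. That call was lost without lipid-laden library 221 (camera adjusted p = 0.418). The MDM markers were not called (camera adjusted p = 0.115), with a median of 0.23 and a mean of -0.21, and the progenitor and glioma list, at a median of -0.23 with an upward test, was not called either (camera adjusted p = 0.78).

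Markers of other cells and of RNA quality moved with lipid load in microglia. The mural and fibroblast list had 10 of 10 genes positive (median 2.74, camera adjusted p = 3.51e-05, adjusted p = 0.227 with an estimated correlation), with Col1a1 and Col1a2, both collagen genes, at 3.45 each (SE 1.07 and 1.08), and 2 genes higher when adjusted over the list alone. The dendritic cell list had 12 of 12 negative (median -1.42, or -1.39 with bounds, camera adjusted p = 0.0148, adjusted p = 0.309 with an estimated correlation), with Dpp4 at 0 against 109 counts (at least 40.0-fold lower) and 2 genes lower when adjusted over the list alone. It lost its call without lipid-laden library 221 (camera adjusted p = 0.106). Mitochondrially encoded RNA was positive for 10 of 10 genes (median 0.42, camera adjusted p = 1.14e-05, adjusted p = 0.158 with an estimated correlation), with mt-Co1 at 0.41 (SE 0.15). With the replicate block, the estimated-correlation p was under 0.05 for the hypoxia and glycolysis, lipid uptake and disease-associated lists (adjusted p = 0.0146 each with an estimated correlation), the immediate early list (0.0187) and the fatty acid oxidation list (0.0387).

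Lipid-laden MDM were compared with non-lipid-laden MDM in the same way. Lpl rose to 150 ± 39.4 CPM (SD, n = 3 against 4, log2 fold change 2.48, SE 0.27, edgeR adjusted p = 7.91e-05). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) rose from 318 ± 31.9 to 802 ± 71.9 CPM (1.33, SE 0.16, edgeR adjusted p = 0.000163), and Abca1 from 252 ± 7.92 to 630 ± 185 CPM (1.32, SE 0.17, edgeR adjusted p = 0.000242). Plin2 rose from 765 ± 149 to 1426 ± 244 CPM (0.90, SE 0.24, edgeR adjusted p = 0.0313) and Gpnmb from 119 ± 59.9 to 757 ± 266 CPM (2.67, SE 0.75, edgeR adjusted p = 0.0387). Ccr2 fell from 959 ± 243 to 215 ± 65.3 CPM (-2.16, SE 0.56, edgeR adjusted p = 0.0272), while P2ry12 (1.73, SE 0.31, edgeR adjusted p = 0.00282) and Tmem119 (1.54, SE 0.32, edgeR adjusted p = 0.00679) rose. In all, 1213 genes were called, 773 higher and 440 lower with lipid load, of which 580 and 283 changed at least 2-fold. The balance depended on the fit: limma-voom called 713 higher and 747 lower, edgeR on only the groups compared 569 and 607, and DESeq2 1131 and 851.

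Of 35 lysosome genes 22 rose and none fell, 23 when adjusted over the list alone (median 0.75, camera adjusted p = 2.18e-20, adjusted p = 0.0128 with an estimated correlation). Examples were Cd63, a tetraspanin of late endosomes (1.43, SE 0.13), and the cathepsin genes Ctsb (1.13, SE 0.11) and Ctsl (1.24, SE 0.13). Of 19 lipid uptake genes 11 rose, 12 when adjusted over the list alone (median 1.22, camera adjusted p = 1.23e-07, adjusted p = 0.0128 with an estimated correlation), with Cd68 at 0.76 (SE 0.10) and the efferocytosis receptor Mertk at 1.22 (SE 0.20). Of 23 disease-associated and lipid-associated genes, 5 of which are on the lipid uptake list and 4 on the lysosome list, 14 rose and 1 fell, with 16 and 1 when adjusted over the list alone (median 1.02, camera adjusted p = 1.21e-11, adjusted p = 0.00551 with an estimated correlation). Of the NRF2 and iron list 4 of 18 rose, 7 when adjusted over the list alone. The 4 were Hmox1 (1.76, SE 0.17), the iron exporter Slc40a1 (2.97, SE 0.38), the glutathione synthesis gene Gclm (1.92, SE 0.39) and Blvrb (1.00, SE 0.21). The median was 0.58 (camera adjusted p = 0.000275, adjusted p = 0.156 with an estimated correlation).

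Of 16 LXR targets and efflux genes 6 rose and 1, Smpdl3a (-0.86), fell, with 8 and 1 when adjusted over the list alone. The higher included the cholesterol transporters Abcg1 (0.97) and Npc1 (1.14). The median was 0.42 (camera adjusted p = 0.00326, adjusted p = 0.343 with an estimated correlation). Of 25 cholesterol synthesis genes 5 fell, with 6 lower and 1 higher when adjusted over the list alone (median -0.58, camera adjusted p = 0.000157, adjusted p = 0.128 with an estimated correlation). They included Cyp51 (-1.53, SE 0.23), Pmvk (-1.36, SE 0.22) and Srebf2, the transcription factor of sterol synthesis (-1.90, SE 0.39). Apoe, a lipid carrier of high abundance (12419 ± 457 and 16892 ± 2468 CPM; 0.44, SE 0.16, edgeR adjusted p = 0.0957, or 0.0245 when only the groups compared entered the fit), the fatty acid receptor gene Cd36 (1.60, SE 1.32, edgeR adjusted p = 0.525) and Itga4 (-1.06, SE 0.93, edgeR adjusted p = 0.561) did not pass. Spp1 (0.94, SE 0.29, edgeR adjusted p = 0.0603) passed with the block (edgeR adjusted p = 0.00429), with only the groups compared (0.0148), without a filter on low counts (0.0477), with DESeq2 (0.0180) and with limma-voom (0.0358). The lipid droplet list was not called (camera adjusted p = 0.883), and Plin2 was its single called member, also when adjusted over the list alone.

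All 13 MHC class II genes had a negative value, and 7 fell, 9 when adjusted over the list alone (median -1.83, camera adjusted p = 7.45e-18, adjusted p = 0.0128 with an estimated correlation). Among them were H2-Oa (-3.00, SE 0.32), H2-DMb2 (-3.02, SE 0.33) and H2-Ob (-2.51, SE 0.31). Of 12 dendritic cell genes 6 fell, with 9 lower and 1 higher when adjusted over the list alone (median -3.12, camera adjusted p = 1.26e-10, adjusted p = 0.02 with an estimated correlation). Among them were Kmo (-3.57, SE 0.44), Ccr7 (-3.24, SE 0.52), Dpp4 (-3.00, SE 0.60) and Zbtb46, a transcription factor of conventional dendritic cells (-3.82, SE 0.81). Of 24 MDM markers 5 fell, with 6 lower and 1 higher when adjusted over the list alone (median -1.04, camera adjusted p = 1.6e-07, adjusted p = 0.0814 with an estimated correlation). Among them were Plac8 (-3.19), Ms4a4c (-1.72), Ccr2 and Ahnak (-1.52). Interferon response genes (3 of 27 fell, also when adjusted over the list alone, among them Ifitm3 at -1.17 and Isg20 at -1.66; median -0.33, camera adjusted p = 0.000876) had adjusted p = 0.517 with an estimated correlation. Endoplasmic reticulum stress genes (2 of 16 fell, also when adjusted over the list alone, Herpud1 at -1.03 and Sesn2 at -1.08; median -0.21, camera adjusted p = 0.0413) had adjusted p = 0.343 with an estimated correlation, and lost their call without lipid-laden library 224 (camera adjusted p = 0.169) or 718 (0.0540) and without non-lipid-laden library 221 (0.0577) or 718 (0.0904). Of 18 immediate early genes 1, Btg2, fell (-1.40), also when adjusted over the list alone (median -0.42, camera adjusted p = 0.00199, adjusted p = 0.509 with an estimated correlation, and camera adjusted p = 0.0716 without lipid-laden library 221).

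Microglial and other-cell genes were also higher in lipid-laden MDM. Of 22 homeostatic microglia genes 15 rose, 18 when adjusted over the list alone (median 1.49, camera adjusted p = 8.26e-11, adjusted p = 0.202 with an estimated correlation). Among them were Sall1 (2.55, SE 0.32), Gpr34 (2.17, SE 0.34) and Ecscr (2.40, SE 0.39). Of 26 proliferation genes 18 rose, 22 when adjusted over the list alone. Examples were Ccnb1 (2.65, SE 0.32), Cdc20 (1.95, SE 0.29) and Rrm2 (1.78, SE 0.31). The median was 1.71 (camera adjusted p = 3.74e-14, adjusted p = 0.142 with an estimated correlation). Of 17 progenitor and glioma cell genes 5 rose, 14 when adjusted over the list alone (median 3.09, or 2.37 with bounds, camera adjusted p = 0.00055, adjusted p = 0.364 with an estimated correlation). Among them were Cspg4 (2.35), Ptprz1 (3.16), Tnr (4.37) and Pdgfra (3.38). Tnr was not called with the block (edgeR adjusted p = 0.0673). Mitochondrially encoded RNA was not called (camera adjusted p = 0.08) but passed with the block (camera adjusted p = 0.0251, adjusted p = 0.401 with an estimated correlation).

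**Figure D3:**
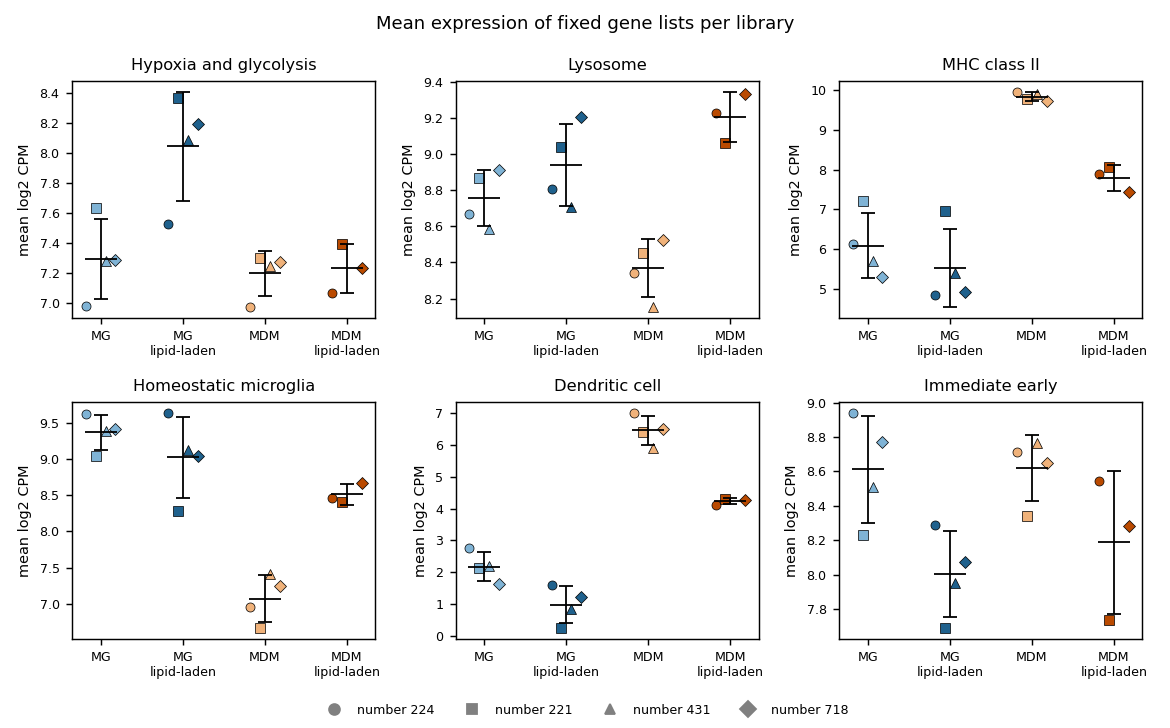
Mean log2 CPM per library of the members of 6 gene lists by group, with lines at the mean ± SD over libraries. The lists are hypoxia and glycolysis, lysosome, MHC class II, homeostatic microglia, dendritic cell, and immediate early and dissociation response. Marker shape gives the replicate number. The median log2 fold change with lipid load was 0.75 for lysosome and -1.83 for MHC class II genes in MDM, and 0.69 for hypoxia and glycolysis and -0.65 for immediate early genes in microglia.

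Among the genes with the largest increase were Lox with 135 counts against 0 (at least 58.6-fold higher), the collagen gene Col1a1 (5.71, SE 1.43), Tmem44 (5.26), Fkbp14 (4.76), the neural adhesion gene Cntn1 (4.62, SE 0.62, edgeR adjusted p = 0.000326), Igfbp2 (4.54), Plpp3 (4.50), Cdk18 (4.46) and the brain proteoglycan gene Ncan (4.31, SE 0.73, edgeR adjusted p = 0.00193). Retnlg, a neutrophil gene (5.31, edgeR adjusted p = 0.0363), rested on lipid-laden library 224 (log2 fold change 1.03, edgeR adjusted p = 0.788 without it) and was not called with the block (edgeR adjusted p = 0.171). The largest decreases were of Cdh1, the E-cadherin gene (-4.54, SE 0.93, edgeR adjusted p = 0.0066), Vdr (-4.33), Klri2 (-4.28), Klrd1, an NK receptor subunit (-4.25, SE 0.55, edgeR adjusted p = 0.000585), the chemokine gene Ccl22 (-4.21), Dcstamp (-4.09), Slc52a3 (-3.96), Epcam (-3.83, SE 0.72, edgeR adjusted p = 0.00376), Zbtb46 and Ppp1r1a (-3.81). The number of calls fell to 657 without lipid-laden library 718 and to 800 without non-lipid-laden library 224. Leaving out single libraries ended the calls of Gpnmb and Dcstamp (any of the 7, edgeR adjusted p at least 0.0518 and 0.0631), and of Plin2 (lipid-laden 224 or 718, non-lipid-laden 221, 224 or 431, 0.0681 to 0.126) and Ccr2 (any 1 lipid-laden library, non-lipid-laden 224 or 718, 0.0547 to 0.122). It also ended those of Ccl22 (any but non-lipid-laden 431, edgeR adjusted p = 0.0858 to 0.133), Slc52a3 (any but lipid-laden 221, 0.0600 to 0.134) and Plpp3 (any but lipid-laden and non-lipid-laden 221, 0.0504 to 0.0651). Col1a1 lost its call without lipid-laden 718 or non-lipid-laden 224, 431 or 718 (edgeR adjusted p = 0.0587 to 0.0669), Vdr without any 1 lipid-laden library or non-lipid-laden 431 (0.0577 to 0.0897), Ppp1r1a without lipid-laden 224 (0.0568) or 718 (0.0643), and Retnlg also without any 1 non-lipid-laden library (0.0778 to 0.0907). With limma-voom, Col1a1 (adjusted p = 0.257), Retnlg (0.347), Tmem44 (0.124), Igfbp2 (0.0726) and Plpp3 (0.0517) were not called. Ccl22 (adjusted p = 0.157) and Dcstamp (0.0913) were not called with DESeq2, and Plpp3 (0.0844) and Cdk18 (0.0757) were not in edgeR on only the groups compared.

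Whether lipid load went with different changes in MDM and microglia was tested as a difference of effects. It was found for 375 genes, 237 with a more positive and 138 with a more negative effect in MDM, for 960 with DESeq2 and for 657 with the replicate block, which became 58 without the libraries of number 718. P2ry12 (difference 2.22, SE 0.42, edgeR adjusted p = 0.0106), Tmem119 (1.95, SE 0.43, edgeR adjusted p = 0.0256), Trem2 (1.32, SE 0.22, edgeR adjusted p = 0.00474), Abca1 (1.10, SE 0.23, edgeR adjusted p = 0.019) and Lpl (1.64, SE 0.36, edgeR adjusted p = 0.0245) changed more upward in MDM. All of these were lower in non-lipid-laden MDM than in microglia, so microglial RNA could also raise them. For Plin2 (0.37, SE 0.33, edgeR adjusted p = 0.639), Gpnmb (0.68, SE 1.00, edgeR adjusted p = 0.81), Spp1 (0.05, SE 0.40, edgeR adjusted p = 0.987), Apoe (0.44, SE 0.21), Cd36 (1.37, SE 1.79), Ccr2 (-0.96, SE 0.78) and Itga4 (0.41, SE 1.32, the last 4 with edgeR adjusted p of 0.327 or more) no difference was detected.

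Of 22 homeostatic microglia genes 14 differed, 18 when adjusted over the list alone, all more upward in MDM, such as Sall1 (2.97). The median was 1.70 (camera adjusted p = 3.23e-14, adjusted p = 0.203 with an estimated correlation). Of 35 lysosome genes 7 did so, 16 when adjusted over the list alone, led by Cd63 (1.29), Ctsl (1.15) and Ctsb (0.92). The median was 0.58 (camera adjusted p = 8.99e-11, adjusted p = 0.131 with an estimated correlation). Of 23 disease-associated and lipid-associated genes 6 did so, with 10 upward and 2 downward when adjusted over the list alone (median 0.67, camera adjusted p = 5.78e-05, adjusted p = 0.131 with an estimated correlation). Of 19 lipid uptake genes 3 did so, Trem2, Mertk (1.60) and Lpl, and 4 when adjusted over the list alone (median 0.75, camera adjusted p = 0.00395, adjusted p = 0.204 with an estimated correlation). Of 26 hypoxia and glycolysis genes 6 changed more downward in MDM, 9 when adjusted over the list alone, led by Ndrg1 (-3.85, SE 0.56), Bhlhe40 (-2.14), Ankrd37 (-2.27) and Ldha (-0.84). The median was -0.63 (camera adjusted p = 9.13e-08, adjusted p = 0.353 with an estimated correlation). Of 13 MHC class II genes 4 did so, 7 when adjusted over the list alone, led by H2-Ob (-2.47), H2-Oa (-2.52) and H2-DMb2 (-2.40). The median was -1.90 (camera adjusted p = 1.04e-08, adjusted p = 0.131 with an estimated correlation). Proliferation (median 1.28, 4 genes, 13 when adjusted over the list alone) and progenitor and glioma genes (3.27, 0 genes, 9 when adjusted over the list alone) were called upward, and MDM markers (-1.03, 3 genes, 7), cholesterol synthesis (-0.57, 3 genes, 4), interferon response (-0.38, 2 genes, 3) and oxidative phosphorylation genes (-0.26, 0 genes, 0) downward (camera adjusted p = 2.01e-08, 0.00112, 5.78e-05, 0.000237, 0.00017 and 6.12e-05). With an estimated correlation these had adjusted p = 0.353, 0.488, 0.204, 0.203, 0.559 and 0.488, so that no list held.

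By size, the genes with a more positive effect in MDM were Lox (fitted difference 7.16), Kynu (6.27), Tmem44 (5.41), Cntn1 (5.00) and Ncan (4.85), and those with a more negative effect were Vdr (-11.35), the oxysterol hydroxylase Cyp7b1 (-5.96), Ppm1j (-4.54), AA467197 (-4.20) and Ifitm6 (-4.19). The values of Lox, Kynu and Vdr depended on the prior count of the fit, since 1 group had 0 counts for each: Lox had 420, 1120, 0 and 135 counts in non-lipid-laden and lipid-laden microglia and MDM, Kynu 98, 0, 2698 and 795, and Vdr 0, 68, 2500 and 99. The count of 375 became 186 without lipid-laden MDM library 718, 245 without lipid-laden MDM library 224 and 231 without non-lipid-laden microglial library 224. The call of Kynu was lost without any 1 of 12 libraries (all but non-lipid-laden MDM 221 and non-lipid-laden microglia 431 and 718, edgeR adjusted p = 0.0508 to 0.0704). Those of Abca1 (edgeR adjusted p = 0.0677 and 0.0733), Tmem119 (0.0575 and 0.0818) and, for 718 alone, Lpl (0.0672), Ppm1j (0.0646) and Tmem44 (0.0680) were lost without lipid-laden MDM library 224 or 718. Further losses were of Tmem119 without non-lipid-laden microglial library 224 (edgeR adjusted p = 0.0545), of Lpl without lipid-laden MDM 221, non-lipid-laden MDM 224 or non-lipid-laden microglia 224 (0.0517 to 0.0650), and of Cyp7b1 without MDM 224 of either kind, lipid-laden microglia 431 or non-lipid-laden microglia 718 (0.0517 to 0.0742). With limma-voom, Lox (adjusted p = 0.149), Kynu (0.165), Tmem44 (0.226), Ncan (0.0532), Cyp7b1 (0.0752) and Ifitm6 (0.111) were not called.

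The calls shared by both origins were counted. Without the block there were no calls in microglia and so 0 shared. With the block, 16 of the 60 genes higher in lipid-laden microglia were also among the 908 higher in lipid-laden MDM (3.67 expected for independent lists, one-sided Fisher exact p = 3.94e-07), and 4 were called lower there. Of the 59 lower genes, 23 were also among the 621 lower in lipid-laden MDM (2.47 expected, one-sided Fisher exact p = 4.64e-17), and 5 were called higher there. Genes are not independent replicates and both lists came from the same fit, so the Fisher p-values do not measure reproducible sharing. Across the 14843 genes, the log2 fold changes of both contrasts correlated weakly (Pearson r = 0.106, Spearman rho = 0.0990), and 52.8% had the same sign.

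Lipid-laden MDM and lipid-laden microglia were compared last. Ccr2 was at 215 ± 65.3 CPM in MDM and 3.70 ± 2.95 in microglia (5.85, SE 0.63, edgeR adjusted p = 0.000128) and Itga4 at 36.2 ± 16.4 against 1.21 ± 2.06 CPM (4.89, SE 1.07, edgeR adjusted p = 0.0206). Lpl was lower in MDM, at 150 ± 39.4 against 461 ± 87.7 CPM (-1.62, SE 0.28, edgeR adjusted p = 0.00392). Trem2 (-0.19, SE 0.16), Abca1 (-0.01, SE 0.17), P2ry12 (-0.51, SE 0.31), Tmem119 (-0.44, SE 0.32), Plin2 (0.27, SE 0.24), Gpnmb (0.19, SE 0.73), Spp1 (0.43, SE 0.29) and Cd36 (-0.06, SE 1.31) did not pass (edgeR adjusted p of 0.495 or more). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) did not pass either (0.55, SE 0.16, edgeR adjusted p = 0.0754), except with the block (edgeR adjusted p = 0.0475), DESeq2 (adjusted p = 0.0288) and limma-voom (0.0370). In all, 413 genes were called, 327 higher and 86 lower in MDM, 271 and 65 at least 2-fold. DESeq2 called 515 higher and 283 lower.

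Of 24 MDM markers 13 were higher in MDM, 19 when adjusted over the list alone (median 2.43, camera adjusted p = 1.97e-19, adjusted p = 0.0157 with an estimated correlation). Among them were the lysozyme gene Lyz2 (1.54, SE 0.19), Tgfbi (1.87, SE 0.24) and Ms4a7 (4.22, SE 0.55). Of 26 hypoxia and glycolysis genes 8 were lower and 1, Bhlhe40 (1.10), was higher, with 22 and 1 when adjusted over the list alone (median -0.66, camera adjusted p = 3.5e-15, adjusted p = 0.158 with an estimated correlation, and 0.0315 with that and the block). Among them were the vasodilator gene Adm (-2.88, SE 0.58), Ankrd37 (-1.59) and the glucose transporter Slc2a1 (-1.25). Of 12 dendritic cell genes 7 were higher, also when adjusted over the list alone (median 3.75, camera adjusted p = 1.49e-05, adjusted p = 0.158 with an estimated correlation). Of 15 T and NK cell genes 5 were higher, or 8 when adjusted over the list alone (median 3.86, or 4.07 with bounds, camera adjusted p = 3.67e-08, adjusted p = 0.115 with an estimated correlation, and 0.0315 with that and the block). Of 13 MHC class II genes 2, H2-DMb2 (2.95, SE 0.32) and Cd80 (2.25, SE 0.47), were higher, 6 when adjusted over the list alone (median 1.93, camera adjusted p = 1.12e-08, adjusted p = 0.115 with an estimated correlation). Of 22 homeostatic microglia genes 4 were lower, 7 when adjusted over the list alone. The 4 were Golm1 (-1.13), Sall1 (-1.31), Bin1 (-0.71) and Ecscr (-1.52). The median was -0.49 (camera adjusted p = 3.6e-06, adjusted p = 0.422 with an estimated correlation). Of 22 immunoregulatory genes, Il10 (4.21) and Chil3 (7.01) were higher and Hmox1 (-0.84) lower, with 8 and 1 when adjusted over the list alone (median 0.69, or 0.73 with bounds, camera adjusted p = 0.000921, adjusted p = 0.265 with an estimated correlation).

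Other lists were called with few or no genes passing. Of 17 progenitor and glioma genes 2, Nes (-3.00, SE 0.55) and Cspg4 (-2.43, SE 0.57), were lower (median -1.29, camera adjusted p = 9.2e-05, adjusted p = 0.38 with an estimated correlation). Of 10 mitochondrially encoded genes 1, mt-Nd5 (-0.88), was lower, 6 when adjusted over the list alone (median -0.68, camera adjusted p = 3.6e-06, adjusted p = 0.167 with an estimated correlation). Proliferation (median -0.48, camera adjusted p = 5.57e-06) and mural and fibroblast genes (median -2.72, camera adjusted p = 0.00397) had 0 called genes and adjusted p = 0.422 each with an estimated correlation. Interferon response genes (median 0.29, camera adjusted p = 0.0111, adjusted p = 0.685 with an estimated correlation) lost their call without lipid-laden MDM library 718 (camera adjusted p = 0.144) or lipid-laden microglial library 224 (0.153) or 431 (0.0588). Endoplasmic reticulum stress genes (median -0.27, camera adjusted p = 0.0171, adjusted p = 0.322 with an estimated correlation), with Trib3 as the single called gene, did so without lipid-laden MDM library 224 (camera adjusted p = 0.121) or lipid-laden microglial library 431 (0.127). The disease-associated (camera adjusted p = 0.112), immediate early (0.197) and endothelial (0.29) lists were called only with the block (camera adjusted p = 0.0384, 0.0173 and 0.00896). These calls were lost with an estimated correlation (adjusted p = 0.219, 0.350 and 0.306 with the block).

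The largest increases in lipid-laden MDM were of genes with 0 counts in lipid-laden microglia: Dpp4 (at least 432-fold), the lectin gene Cd209a (at least 360-fold), P2ry10 (at least 341-fold), Kynu (at least 336-fold), Hepacam2 (at least 220-fold), the granzyme gene Gzma (at least 179-fold), Ms4a8a (at least 147-fold), Plet1 (at least 132-fold) and Klrd1 (at least 119-fold). Kmo had 850 counts against 1, a ratio of 1076 (counting interval 193 to 42565). The largest decreases were of Nes, a gene of neural progenitors, Adm, Cdk18 (-2.86), Rasal2 (-2.63), Cspg4, Fkbp14 (-2.40), Trib3 (-2.40), Trpm4 (-2.23), Selenbp1 (-2.11, SE 0.32, edgeR adjusted p = 0.00173) and Klhl3 (-2.06). Trib3 was not called with the block (edgeR adjusted p = 0.0627) or limma-voom (adjusted p = 0.112). Trib3 (edgeR adjusted p = 0.103), Klhl3 (0.0644) and Itga4 (0.103) were not when only the groups compared entered the fit. The count of 413 became 168 without lipid-laden MDM library 224, 261 without lipid-laden MDM library 718, 243 without lipid-laden microglial library 431 and 176 when only the groups compared entered the fit. Leaving out any 1 of the 7 libraries ended the calls of Cdk18 (edgeR adjusted p = 0.0541 to 0.223) and Fkbp14 (0.0651 to 0.164), and any but lipid-laden microglia 224 that of Trib3 (0.0508 to 0.222). The call of Cspg4 was lost without any 1 lipid-laden MDM library or lipid-laden microglia 431 or 718 (edgeR adjusted p = 0.0572 to 0.178), that of Klhl3 without MDM 224 or 718 or microglia 221, 431 or 718 (0.0570 to 0.178), that of Rasal2 without any 1 MDM library (0.0520 to 0.0827) and that of Trpm4 without MDM 221 or 718 or microglia 431 (0.0523 to 0.0926). Without lipid-laden MDM library 224, Adm (edgeR adjusted p = 0.0917), Nes (0.0542), Cd209a (0.0692) and Itga4 (0.0917) were not called, nor were Adm without MDM 718 (0.0676) and Itga4 without lipid-laden microglia 224 (0.0532).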

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

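Of the tests in this part, the splits of the libraries, except the swaps of microglia alone, and the correlation of gain shares between numbers were set before their result was seen, and the others were chosen after it was seen.

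In groups of 4 libraries, 22 of 314 checks (7.01%) found 1 library far from the other 3, where chance gives about 1 in 20. Among non-lipid-laden microglia, the mean log2 CPM of the progenitor and glioma list was 2.22 in library 431 (others 3.95 to 4.09), and that of the mural and fibroblast list -1.35 in library 224 (others 1.41 to 1.90). In the same group, CPM stood apart for Abca1 in library 431 (441, others 572 to 597), Cd36 in 221 (291.9, others 1.26 to 33.7), Cd209a in 224 (11.9, others 0), AA467197 in 221 (6.61, others 3.12 to 3.29) and Cass4 in 224 (60.8, others 40.3 to 43.5). Among lipid-laden microglia, mitochondrially encoded RNA had a mean log2 CPM of 6.44 in library 718 (others 6.74 to 6.77). CPM stood apart for Cd36 in library 221 (349, others 10.1 to 22.4), Itga4 in 718 (4.27, others 0 to 0.557), Retnlg in 224 (9.80, others 0 to 1.31), Fkbp14 in 221 (33.6, others 22.6 to 24.2) and Cdk18 in 221 (57.4, others 18.3 to 24.3). The same held for Dcstamp in 431 (4.53, others 0 to 0.201), Smtnl2 in 224 (5.90, others 25.1 to 27.5) and Cspg4 in 718 (76.2, others 37.2 to 42.2). Among non-lipid-laden MDM, library 431 had 15127 genes detected (others 16486 to 16560). Library 224 had a mean log2 CPM of 7.84 for the disease-associated and lipid-associated list (others 8.20 to 8.23) and of 6.97 for the hypoxia and glycolysis list (others 7.25 to 7.30). CPM stood apart for Gpm6a in 718 (2.99, others 0 to 0.466), Plet1 in 221 (162, others 52.4 to 59.8) and Igf1 in 221 (81.9, others 21.2 to 30.7). Cd36 was high in both microglial libraries of number 221. The cause of these values was not tested.

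The effect of lipid load differed between MDM and microglia for 375 genes by a test of the difference itself. The named genes were Lox (fitted difference 7.16), Kynu (6.27), Tmem44 (5.41), Cntn1 (5.00), Ncan (4.85), P2ry12 (2.22), Tmem119 (1.95), Lpl (1.64), Trem2 (1.32) and Abca1 (1.10) toward a higher effect in MDM. Toward a lower one they were Vdr (-11.35), Cyp7b1 (-5.96), Ppm1j (-4.54), AA467197 (-4.20) and Ifitm6 (-4.19). Of 100 splits of the libraries drawn without regard to the numbers, the real one included, 4 gave at least 375 genes (highest other 494). Of 100 drawn from the 128 swaps of lipid load within numbers, which part all 7 pairs as the real split does, 3 did so (highest other 749). By these shares, chance can be excluded only for the assignment of lipid load to all libraries together. That is not the question of a different effect in the 2 origins. Each other split that reached 375 left the MDM libraries in place, and those that moved them gave at most 29 and 18 genes. So the splits of all libraries cannot exclude chance for the difference of effects. Swapping lipid load within the numbers of microglia alone gave 194 to 749 genes, 3 of the 16 reached 375, and 16 are too few for a share under 0.05.

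Over splits that ignore the numbers, the real split of the 7 MDM libraries by lipid load alone, among 35, gave as many as 1213 genes (highest other 194). The same held for MDM against microglia without lipid load (3442 genes, highest other 0, 1 of 35 splits) and with it (413 genes, highest other 104, 1 of 35 splits). These shares lie under 0.05, but they would exclude chance only if the numbers did not pair the libraries. The splits that part as many pairs as the real one are 8 for each contrast, too few for a share under 0.05. Their highest other counts were 102, 0 and 2, so with the pairing kept, chance could not be excluded by splits. For lipid load in microglia, where edgeR called 0 genes (1367 at an unadjusted p under 0.05, DESeq2 164, limma-voom 0), all 35 splits reached that count by construction (highest other 29), so they say nothing about chance. With the replicate block, the 8 splits are too few for a share under 0.05: the real split gave 119 genes, 1 of the 8 reached that, and the highest other gave 0.

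Lipid-laden MDM lay between non-lipid-laden MDM and microglia: for 124 genes specific to microglia they had gained a median share of 0.397 of the distance from non-lipid-laden MDM to lipid-laden microglia (quartiles 0.283 and 0.508), while 244 genes specific to MDM had lost a median share of 0.813 of that distance. Both sets were picked from these same libraries, by a log2 fold change over 3 in size between non-lipid-laden MDM and microglia. They also needed at least 20 CPM, so the choice of genes can tilt the shares. In each of the 3 numbers the loss of these genes exceeded the gain, by at least 0.336. In number 221, 21 homeostatic microglia genes gained 1.12, more than the loss of 0.827, so the shares decide nothing there. In numbers 224 and 718 the loss (0.788 and 0.842) exceeded both gains. For the genes picked, this argues against a mix of microglia and the cells of the non-lipid-laden MDM libraries as the whole cause. Gain shares correlated between numbers at a mean Spearman rho of 0.197 across genes (interval 0.0756 to 0.311), so microglia among the sorted cells as the source of the microglial transcripts could not be told apart from expression by the MDM themselves, since the interval spans the bound set for it. Whether RNA of progenitor and glioma cells was carried along with microglial RNA stays open. Of the 17 genes of their list, 5 were called lower in non-lipid-laden MDM and had at least 20 CPM in lipid-laden microglia. These 5 had a gain share within the quartiles of the microglia-specific genes (0.389). In numbers 221, 224 and 718 theirs (0.328, 0.268 and 0.259) lay below that of the microglia-specific genes (0.491, 0.281 and 0.386). By the same filter, 21 homeostatic microglia genes had 0.512 (1.12, 0.249 and 0.610), above the upper quartile. A change of the MDM toward a microglial state stays open.

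Dendritic cell and MHC class II genes were lower in lipid-laden MDM, with medians of -3.12 over 12 genes and -1.83 over 13. Dilution by microglia at the largest median gain share of the microglia-specific genes in any number, 0.491, would lower a gene absent from microglia by no more than -0.98 on the log2 scale, which argues against dilution as the whole cause. Homeostatic microglia genes had larger shares in numbers 718 (0.610, a bound of -1.36, against means of -2.23 and -2.30 for the 2 lists) and 221 (1.12, which gives no bound). The dendritic cell list fell further than the MDM markers in 3 of 3 numbers, which is consistent with fewer dendritic-like cells among those sorted as lipid-laden, while lower expression per cell was not tested and stays open.

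Hypoxia and glycolysis genes were higher in lipid-laden microglia in each of the 4 numbers (mean log2 differences over the 26 genes of 0.54, 0.74, 0.81 and 0.90 in numbers 224, 221, 431 and 718). RNA of glioma cells as the whole cause could not be told apart, since the progenitor and glioma list had a negative mean difference in 2 of these numbers (-1.12 and -0.44) and a positive one in the others (0.54 and 0.39). Nor could RNA of mural cells and fibroblasts: the summed CPM gained by the hypoxia list was 11.999 to 107 times that gained by the mural list, but how much hypoxia RNA such cells carry is not known here. A response of the microglia to low oxygen or to lipid stays open as untested.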

How the results depend on the processing

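The alternatives with the replicate block combined with another tool or without all libraries of a number, and the fit without both lipid-laden libraries numbered 221, were chosen after seeing the data. Across all alternatives, 1994 values of named genes kept their direction and their side of the threshold. There were 146 that no longer passed (125 of them without 1 library and 21 under other settings), 34 that newly passed (7 and 27), and 45 that changed sign, all of genes and contrasts not called. Of the values of called lists, 807 kept both and 113 no longer passed (18 without 1 library, 95 under other settings), and none changed sign.

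Libraries left out singly are those of the groups compared unless others are named. For lipid load in microglia, edgeR called 0 genes (1367 at an unadjusted p under 0.05), limma-voom 0 and edgeR with RLE size factors 0, while DESeq2 called 164, edgeR without a filter on low counts 17 and with the replicate block 119. Leaving out 1 library gave 0 to 64 genes (64 without lipid-laden 224, 2 without non-lipid-laden 431 and 2 without 718). For lipid load in MDM, 1213 genes became 1982 with DESeq2 and 657 to 1052 without 1 library (800 without non-lipid-laden 224, 657 without lipid-laden 718). For MDM against microglia without lipid load, 3442 became 2755 to 3158 without 1 library, and no alternative set in advance moved it by more than 1.5 times. With lipid load, 413 became 798 with DESeq2, 176 when only the groups compared entered the fit, with fewer libraries to estimate the spread, and 168 to 378 without 1 library (168 without MDM 224, 243 without microglia 431, 261 without MDM 718). The difference of effects, 375 genes, became 960 with DESeq2, 657 with the block and 186 to 452 without 1 library (231 without non-lipid-laden microglia 224, 245 without lipid-laden MDM 224, 186 without lipid-laden MDM 718). Without 1 library of the other groups, which share the estimate of the spread, the counts were 0 for lipid load in microglia, 1015 to 1383 in MDM, and 3247 to 3674 and 349 to 431 for MDM against microglia without and with it. Calls shared by lipid-laden microglia and MDM, 0 in edgeR, were 46 with DESeq2, 39 with the block and 0 to 12 without 1 library (12 without lipid-laden microglia 224, 1 and 2 without non-lipid-laden microglia 431 and 718). The cause of these differences was not tested.

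Added alternatives started from the fit with the block. In microglia, 119 genes for lipid load became 602 with DESeq2, 212 with limma-voom, and 17, 68, 13 and 0 without the libraries of number 221, 224, 431 and 718. In MDM, 1529 became 2552 with DESeq2 and 456 to 1326 without a number (761 without 224, 456 without 718). MDM against microglia without lipid load gave 3969, and 2252 to 3346 without a number (2596 without 224, 2252 without 718). With lipid load, 569 became 1204 with DESeq2, 992 with limma-voom and 148 to 438 without a number (217 without 224, 148 without 718). The difference of effects, 657, became 1565, 1025 and 58 to 441 (415 without 221, 362 without 224, 58 without 718). The block and the fit without it shared 1117 calls for lipid load in MDM, 3295 and 370 for MDM against microglia without and with lipid load, and 352 for the difference of effects. The cause was not tested.

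Of 34 lists, camera with the preset correlation called 18 for lipid load in microglia, 15 for lipid load in MDM, 14 and 13 for MDM against microglia without and with lipid load and 12 for the difference of effects. With an estimated correlation it called 1, 5, 2, 1 and 0. Fry called 4 for lipid load in microglia, 7 for MDM against microglia with lipid load and 5 for the difference of effects. Leaving out 1 library gave 16 to 21, 14 to 17, 14 to 16, 11 to 18 and 12 to 13 lists.

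The values that changed sign were these. For lipid load in microglia, Apoe (0.00) was -0.05, -0.02 and -0.10 without lipid-laden 224, lipid-laden 718 and non-lipid-laden 431 (up to 0.13 without another). Trem2 (0.01) was -0.0037 with limma-voom and -0.12, -0.04 and -0.01 without lipid-laden 224, non-lipid-laden 221 and 431 (up to 0.097). Cd36 (0.23) was -2.29 without lipid-laden 221 and -0.11, -0.03 and -0.16 without non-lipid-laden 224, 431 and 718 (up to 2.64 without non-lipid-laden 221). For MDM against microglia without lipid load, Cd36 (-1.44) was 0.30 with limma-voom, 0.18 with the block and 0.97 without microglia 221 (lowest -1.83). Gpnmb (-0.49) was 0.55 without microglia 221 (lowest -0.81), and Plin2 (-0.09) was 0.0045 and 0.092 without MDM 431 and microglia 718. With lipid load, Abca1 (-0.01) was 0.21 and 0.03 without MDM 221 and microglia 718 (lowest -0.17). Cd36 (-0.06) was 0.81 with limma-voom, 0.53 with the block and 0.27, 0.36 and 2.46 without MDM 224, MDM 718 and microglia 221. Gpnmb (0.19) was -0.04, -0.14 and -0.01 without MDM 718, microglia 224 and microglia 431 (0.74 without microglia 221, highest 0.82 with the block).

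For the difference of effects, Ccr2 (-0.96) was 0.24 with limma-voom. Cd36 (1.37) was -0.02 without lipid-laden MDM 221 and -1.03 without non-lipid-laden microglia 221 (highest 3.89), and Gpnmb (0.68) was -0.36 without the latter (highest 1.23). Itga4 (0.41) was -0.022 with the block and -0.03, -0.0025, -0.01 and -0.059 without lipid-laden MDM 224, lipid-laden microglia 221 and 431 and non-lipid-laden microglia 224 (highest 3.09). Spp1 (0.05) was -0.0051 with DESeq2 and with RLE size factors, -0.013 with limma-voom, and -0.13, -0.05, -0.04, -0.12, -0.02 and -0.23 without lipid-laden MDM 224, non-lipid-laden MDM 221, lipid-laden microglia 221 and 224 and non-lipid-laden microglia 431 and 718 (highest 0.25). The cause was not tested.

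Leaving out both lipid-laden libraries numbered 221 moved none of the edgeR counts of genes by more than 1.5 times. Depth limited genes near 0 counts, for which folds are given as bounds against a floor of 3 counts over the group.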

Other observations

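All tests in this part were chosen after the results were seen. The contrast of lipid load in MDM and that of MDM against microglia share the 4 non-lipid-laden MDM libraries, so error in these libraries enters both with opposite sign. Of 773 genes higher with lipid load in MDM, 677 were called lower in non-lipid-laden MDM than in microglia (96.8 for independent lists), and of 440 lower genes 387 were called higher there (47.0). The log2 fold changes correlated at r = -0.713 across genes, which are not independent replicates, with a covariance of -2.54. In 10 simulations without any change, the shared libraries alone gave a mean r of -0.450, a covariance of -0.396 and at most 0 called genes. When the MDM libraries were divided so that each contrast had its own 2, in all 6 ways, r was -0.479 to -0.455, the covariance -2.25 to -2.20, and 60.2 to 82.0% of the 307 to 545 higher genes were called lower against microglia.

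With the replicate block, 43 of the 60 genes called higher in lipid-laden microglia also had a positive value in MDM, and 46 of the 59 called lower a negative one. This counts genes whether or not they were called there. In the fit without the block, the median MDM values of the 60 and the 59 genes were 0.26 and -0.28. The genes called in lipid-laden MDM included 8 above both non-lipid-laden MDM and lipid-laden microglia (Psap, Akap10, Arhgap19, Wwp1, Hacd4, Apobec1, Paox and Nrp1) and 4 below both (Myc, Ndrg1, Atp7b and Ankrd37). Psap encodes the precursor of the saposins, which aid lysosomal lipid breakdown.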
